A study of Homo sapiens with 12 samples.

How the data were processed

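RNA was measured in 12 libraries of human HEK 293 cells, an embryonic kidney line, that carried a GFP-tagged MAB21L1 transgene under tetracycline control. The transgene was wild type (WT) or held the substitution Arg51Leu or Arg51Gln, with 1 cell line per form. Each of the 3 lines was sampled without tetracycline (OFF) and after 12 h with 1 µg/ml tetracycline (ON), with 2 biological replicates in each of the 6 groups. Per the labels' protocols, poly(A) RNA was turned into randomly primed cDNA libraries and read from a single end on an Illumina NextSeq instrument. Whether the library kit kept the strand is not given in the sources used here.

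The authors deposited 1 table of estimated counts (expected counts, which need not be whole numbers) for all 12 libraries. Per the submitters' processing notes, the counts came from Salmon 0.8.2 with the genome build GRCh38; the annotation is not given in the sources used here. The table had 61999 rows and its file did not pair them with gene identifiers or symbols. A row is therefore named here by its position in the table, counted from 1 below the header, and no row was given a gene name. Only 26.8% of the values above 0 were whole numbers within a tolerance of 1e-06. Salmon shares reads that fit several transcripts among them by an estimate, so similar rows trade counts. To mark the most alike of them, pairs of rows with a total of at least 600 counts were compared. Pairs whose values differed by at most 2 counts in every library were listed, and 545 rows belonged to such near-identical sets. Rows that share counts unevenly are not found in this way and were not marked.

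The column names were matched to the samples by their meaning. The names of the protein forms gave the line, the words Negative and Positive were read as without and with tetracycline, and the closing number was read as the replicate number. No column was left without a sample. Over all rows of the table, the library totals ran from 23922874 to 39836542 counts. The Arg51Leu ON libraries were the deepest and the shallowest, while the 10 others held between 25944002 and 29388508 counts.

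Counts were rounded to whole numbers. Rows with too few counts were removed with the filterByExpr function of edgeR 4.0.16 using the 6 groups, which kept 20594 rows holding 99.9% of all counts. A further 22672 rows had some counts and were not tested, and 18733 rows were 0 in all libraries. The median count of a tested row in a library was 350. The library totals of the tested rows were scaled by TMM factors, and levels are given as CPM on these scaled totals. The main test was edgeR's quasi-likelihood F test with robust dispersion estimates and Benjamini-Hochberg adjustment over the tested rows; a row was called at an adjusted p below 0.05. A single model with the 6 groups gave 10 comparisons, and an additive model of line and tetracycline gave the mean response over the lines. The standard error (SE) of a log2 fold was derived from the F statistic. R 4.3.3 was used, and figures were drawn with matplotlib.

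The comparisons were the tetracycline response of each line, the mean response, the differences of the responses between lines, and each mutant line against the WT line with and without tetracycline. Principal components and correlations of fold changes used the rows with a mean log2 CPM of at least 1, with a prior count of 2. The rule for naming genes, the design and most alternatives were set before the data were examined. The rule took, among rows called with a mean log2 CPM of at least 1 and non-overlapping libraries (for the mean response, the same sign in each line), those with the largest folds. It was applied without its condition on gene symbols and limited to 2 rows in each direction per comparison. Where fewer than 5 rows passed, those with the smallest p were taken also without passing. Row 14934 took the first place among higher rows in each response.

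The planned tests of 34 gene lists, and the check of MAB21L1 and its relatives in every library, need gene names and were not run. The direction of the labels was therefore not checked against the transgene. Sets of near-identical rows were treated as uncertain.

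The edgeR test was tried on simulated counts for the comparisons named in this paragraph. Other comparisons, such as the Arg51Gln response, were not tried, and limma-voom and DESeq2 were tried on the WT response only. The counts had the real mean of each line, library sizes and dispersions, and 200 of 20594 rows were changed. The changed rows were drawn from those with a mean log2 CPM of at least 1, so recovery at lower levels was not measured. For the WT response the edgeR test recovered 56% of the rows changed 1.25-fold, 80% of those changed 1.5-fold, 92% at 2-fold and 100% at 3-fold, and 12 of 176 calls were unchanged rows. For the difference of the Arg51Leu and WT responses the recovery was 34%, 70%, 86% and 96% at these folds, and 14 of 157 calls were unchanged rows. For the mean response the recovery was 70%, 94%, 100% and 100%, and 14 of 196 calls were unchanged rows. For Arg51Leu against WT with tetracycline the recovery was 46%, 78%, 96% and 100%, and 8 of 168 calls were unchanged rows. In that simulation the WT means were given to both lines before the change. In simulated data with no change in the Arg51Leu line, its response had 7 calls.

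The alternatives were RLE factors, DESeq2 1.42.0, limma-voom (limma 3.58.1), no filter on low counts, a filter of at least 1 CPM in at least 4 libraries, fits of only the groups compared, the replicate number as a block, the replicate number within each line as a block, an added fold of at least 1.5, and leaving out each library in turn. In the last case the lone library of a group was assumed to vary like the other groups. Thinning all libraries to equal totals, and keeping 1 row of each near-identical set, which removed 310 tested rows, were added after the data had been seen. Leaving a library out, or adding terms, also lowers the residual degrees of freedom. Fisher's exact test was used for overlaps of called rows, one-sided for more shared rows, and genes are not independent in it. Overlaps and correlations of comparisons with the same WT libraries were set beside 20 simulated data sets in which both mutant lines had the WT means.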

Results

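The series addressed how expression of GFP-tagged MAB21L1, and of its forms with the substitutions Arg51Leu and Arg51Gln, changed the RNA content of HEK 293 cells. MAB21L1 is a member of the MAB21 protein family with known roles in eye development, and arginine 51 was replaced in both mutant forms. The data were 12 libraries in 6 groups of 2: the WT, Arg51Leu and Arg51Gln lines, each without tetracycline and after 12 h with 1 µg/ml of it. The total counts were 28718335 and 29388508 for WT OFF, 25944002 and 26397852 for WT ON, 28478175 and 27785162 for Arg51Leu OFF, 39836542 and 23922874 for Arg51Leu ON, 27672370 and 28914844 for Arg51Gln OFF, and 26257719 and 28040415 for Arg51Gln ON. Between 30690 and 33114 rows of the table were above 0 in a library. A row stands for 1 gene or transcript entry without a name, and the files do not pair rows with genes.

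Replicates lay close together. The common biological coefficient of variation between replicates of a group, which leaves out the sampling noise of the counts, was 2.97%. A chi-square statistic per row was 1.89 to 3.04 for the 6 pairs of the same group, 3.59 to 5.72 for the 12 pairs of ON and OFF libraries of the same line, and 6.15 to 16.98 for the 48 pairs from different lines. All pairs thus differed by more than sampling noise, which gives a value near 1, and each library was counted as 1 sample. In the model of the 6 groups, p-values rest on the spread between replicates of a group, estimated jointly over all groups. They hold no spread between lines of the same form. Because each form was carried by 1 line, a difference between forms cannot be separated from a difference between lines. A line without the transgene was not analysed here, so a response includes any effect of tetracycline itself.

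The line was the largest source of variance. Over 14466 rows, differences between lines made up 55.8% of the sum of squares of log2 CPM, ON against OFF within lines 19.2%, and replicates 24.9%. These had 2, 3 and 6 degrees of freedom. The shares are not corrected for them, so the first 2 also hold replicate noise. The first principal component (33.9% of the variance) held the Arg51Gln libraries apart from the 8 others, and the second (22.2%) held the WT libraries apart. The third component (9.34%) separated all 6 OFF from all 6 ON libraries, with OFF values between 3.43 and 9.11 and ON values between -8.4 and -3.98.

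**Figure D1:**
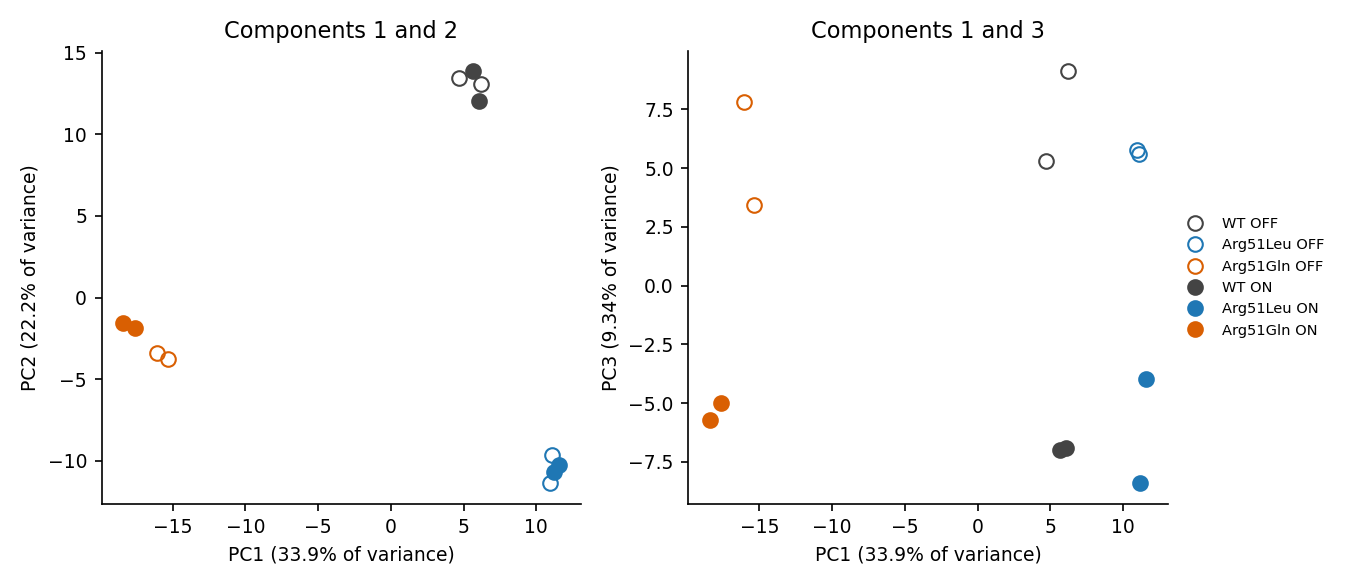
Principal components of log2 CPM, 1 point per library, with PC1 against PC2 on the left and PC1 against PC3 on the right; colours give the line and filled points the ON libraries. PC1 and PC2 separate the 3 lines, and on PC3 all ON libraries lie below all OFF libraries.

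Among called rows with a mean log2 CPM of at least 1, to which the order of named rows by fold is limited throughout, 1 row stood out in the tetracycline response of the WT line. Row 14934 rose from 62.4 ± 0.824 CPM to 538 ± 13.3 CPM (mean ± SD, n = 2), an 8.61-fold change (log2 fold 3.11, SE 0.03, adjusted p = 1.36e-24). Row 53638 rose 1.82-fold from 2.37 ± 0.413 CPM (adjusted p = 0.0337). Row 17333 fell from 18.1 ± 0.348 to 8.27 ± 1.13 CPM, a log2 fold of -1.13 with SE 0.09 (adjusted p = 9.87e-07), and row 57537 fell from 11.7 ± 0.231 to 6.56 ± 0.631 CPM (adjusted p = 0.00182). In all, 60 rows were called, 35 higher and 25 lower, and 8 of them changed at least 1.5-fold. At an unadjusted p below 0.05 there were 2629 rows, where 1030 are due by chance. The balance turned without a WT ON library, to 6 higher and 17 lower rows without replicate 1 and 5 and 10 without replicate 2, and it was 37 and 43 with the filter of 1 CPM in 4 libraries, 138 and 161 with no filter and 55 and 64 with only the WT libraries. The count was 9 and 10 without WT OFF replicate 1 or 2, and 93 without Arg51Leu ON replicate 1. It was 150 with DESeq2 (105 higher and 45 lower) and 9 with limma-voom, where rows 53638 and 57537 were no longer called; without either WT OFF or either WT ON library row 53638 had an adjusted p of 0.089 to 0.222, and without WT OFF or WT ON replicate 2 row 57537 had 0.0516 and 0.0896.

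The same row led the response of the Arg51Leu line within that limit. Row 14934 rose from 34.1 ± 0.331 to 304 ± 4.72 CPM (8.92-fold, log2 fold 3.16, SE 0.03, adjusted p = 5.62e-24), and row 21664 rose from 4.25 ± 0.375 to 7.06 ± 1.08 CPM (adjusted p = 0.0164). Row 21995 fell from 12.7 ± 1.05 to 8.3 ± 0.00431 CPM, a log2 fold of -0.61 (adjusted p = 0.00772). Row 35713 fell from 3.21 ± 0.282 to 1.74 ± 0.0106 CPM (adjusted p = 0.0496), and it belongs to a near-identical set and is uncertain. There were 62 called rows, of which 14 were higher and 48 lower, 9 of them by at least 1.5-fold; 2407 rows had an unadjusted p below 0.05. The lean to lower rows was absent without Arg51Leu ON replicate 1, with 28 higher and 27 lower, and without Arg51Leu OFF replicate 2, with 10 and 9, and smaller with DESeq2, with 39 and 58, and with no filter, with 157 and 174. The count was 14 and 19 without Arg51Leu OFF replicate 1 or 2, and 23 without Arg51Leu ON replicate 2. It was 97 with DESeq2 and 8 with limma-voom, where rows 21664 and 35713 were no longer called. Row 35713 lost its call without any 1 of 11 libraries, all but WT OFF replicate 1, with adjusted p up to 0.246, and with only the Arg51Leu libraries (0.0802); row 21664 lost it without Arg51Leu OFF replicate 1 (0.0612) or 2 (0.132) or Arg51Leu ON replicate 1 (0.11), and row 21995 without Arg51Leu OFF replicate 1 (0.0911).

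In the Arg51Gln line, row 14934 rose from 79.6 ± 0.104 to 895 ± 10.3 CPM (11.2-fold, log2 fold 3.49, SE 0.03, adjusted p = 8.65e-26). Row 19680 rose from 8.5 ± 0.867 to 11.3 ± 0.057 CPM (adjusted p = 0.0339). Row 20577 fell from 3.77 ± 0.71 to 2.11 ± 0.0836 CPM (adjusted p = 0.0459), and row 55015 fell from 9.48 ± 0.14 to 5.88 ± 0.481 CPM (adjusted p = 0.00511). A total of 435 rows were called, 223 higher and 212 lower, but 9 changed at least 1.5-fold, and the median fold of the called rows was 1.12. At an unadjusted p below 0.05 there were 3375 rows. The balance moved to 8 higher and 42 lower without Arg51Gln OFF replicate 1, to 34 and 70 without Arg51Gln ON replicate 1, and to 395 and 578 with no filter. The count was 50 and 9 without Arg51Gln OFF replicate 1 or 2, 104 and 15 without Arg51Gln ON replicate 1 or 2, 261 and 260 without WT ON replicate 1 or 2, and 732 and 701 without Arg51Leu ON replicate 1 or 2. It was 109 with limma-voom, where rows 19680 and 20577 were no longer called. Both also lost their calls without any 1 of the 4 Arg51Gln libraries (adjusted p of 0.0576 to 0.254 and 0.0885 to 0.303), and row 55015 without Arg51Gln OFF or ON replicate 2 (0.052 and 0.0892).

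**Figure D2:**
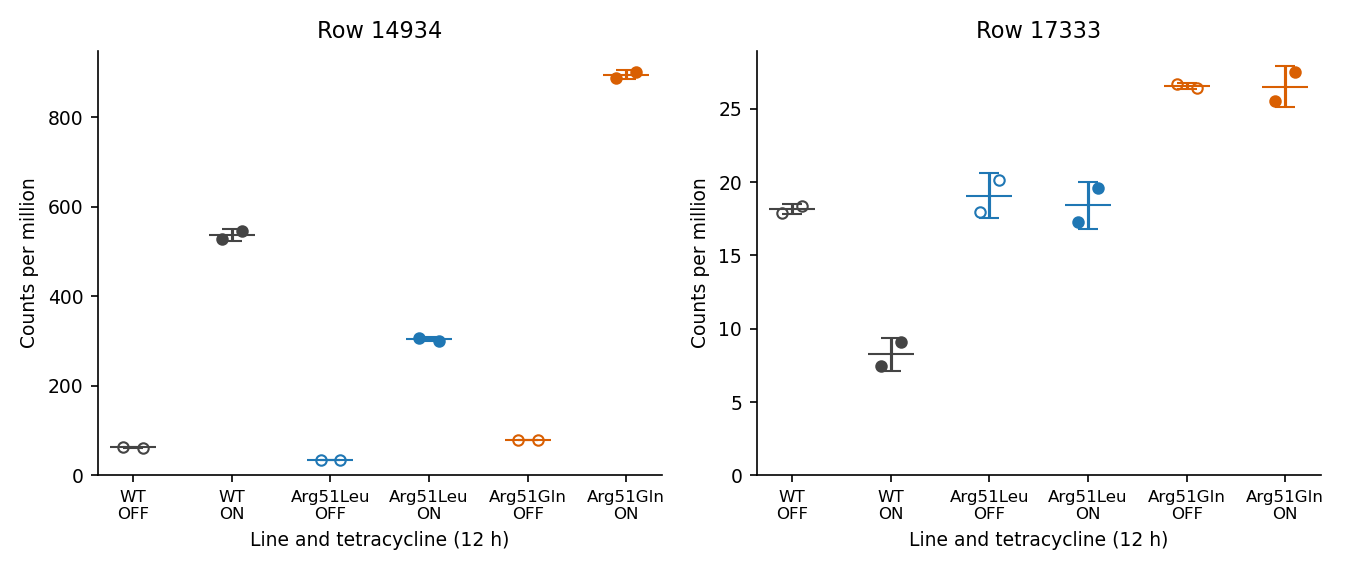
Levels of rows 14934 and 17333 in CPM (linear axes from 0), with 1 point per library, horizontal marks at the group mean and bars of 1 SD (n = 2); open points are OFF and filled points ON. Row 14934 rises in all 3 lines, from 34.1 to 79.6 CPM without and 304 to 895 CPM with tetracycline, and row 17333 falls from 18.1 to 8.27 CPM in the WT line.

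Averaged over the 3 lines, row 14934 rose 9.6-fold (log2 fold 3.26, SE 0.06, adjusted p = 1.28e-07), and the next under the rule for naming rows, row 30657, rose 1.39-fold (adjusted p = 0.0172). Rows with a lower mean level, which the rule leaves out, had larger folds, so that 7 called rows were higher by at least 1.5-fold. The mean level of row 41160 was lower ON than OFF in each line, from 5.42 ± 0.205 to 3.19 ± 0.0545 CPM in WT, 4.04 ± 1.2 to 2.77 ± 0.036 in Arg51Leu and 3.43 ± 0.0775 to 2.25 ± 1.06 in Arg51Gln. Its mean log2 fold was -0.65 (SE 0.13, adjusted p = 0.0049). The row was not called in the WT, Arg51Leu or Arg51Gln response alone (adjusted p of 0.19, 0.414 and 0.262). Row 58281 had a mean log2 fold of -2.12 with SE 0.45 (adjusted p = 0.0243), and its OFF libraries were widely spread, for example 8.82 ± 4.35 CPM in Arg51Gln. The mean response had 1912 called rows, 1109 higher and 803 lower, with a median fold of 1.07; 25 of them changed at least 1.5-fold, of which 7 were higher and 18 lower. Of the 1911 called rows other than row 14934, 1901 (99.5%) had the same sign in the 3 lines, 1540 were called in no single line, 340 in 1, 27 in 2 and 4 in all 3. The same sign in 3 lines is partly built in, because rows were chosen by their mean over those lines. The count was 1260 without Arg51Gln OFF replicate 1, and row 58281 was not called without WT OFF replicate 1, Arg51Leu OFF replicate 2, or any 1 of the Arg51Leu or Arg51Gln ON libraries (adjusted p of 0.0532 to 0.064).

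Rows called in 1 line tended to move the same way in the others. Of the 434 rows called in the Arg51Gln response other than row 14934, 89.6% had the same direction in the WT line and 91.9% in the Arg51Leu line, with median aligned log2 folds of 0.06 and 0.07 there against 0.17 in the Arg51Gln line. The WT and Arg51Leu responses shared 2 higher and 8 lower rows where 0.0238 and 0.0583 are expected for independent lists (Fisher's exact test, p = 0.000252 and 4.95e-16), and 1 row was called in opposite directions. The WT and Arg51Gln responses shared 10 higher and 6 lower rows (Fisher's exact p = 2.62e-12 and 1.67e-07), and the Arg51Leu and Arg51Gln responses shared 5 and 11 (Fisher's exact p = 2.63e-07 and 1.72e-12). These 3 pairs of comparisons have no libraries in common. In all 3 responses 5 rows were called: row 14934, which rose, and 4 that fell by 0.15 to 0.52 on the log2 scale in a line. Among the latter, row 13183 had log2 folds of -0.23, -0.25 and -0.52, and row 12523 had -0.23, -0.21 and -0.24, in WT, Arg51Leu and Arg51Gln; both were chosen after their values were seen. Across 14465 rows, which are not independent, the fold changes of 2 lines had Pearson correlations of 0.19 (WT and Arg51Leu), 0.16 (WT and Arg51Gln) and 0.24 (Arg51Leu and Arg51Gln), and Spearman correlations of 0.39, 0.3 and 0.31 in the same order.

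The responses of the lines were then tested against each other. Row 17333 fell in the WT line, while its mean was 19.1 ± 1.54 CPM OFF and 18.4 ± 1.6 CPM ON in Arg51Leu, and 26.6 ± 0.201 and 26.5 ± 1.41 CPM in Arg51Gln. Its log2 response was 1.07 above the WT response in Arg51Leu (SE 0.12, adjusted p = 0.000595) and 1.13 above it in Arg51Gln (SE 0.12, adjusted p = 0.000108). Row 21664 differed between Arg51Leu and WT by 1.47 (SE 0.19, adjusted p = 0.00146), going from 6.34 ± 0.443 to 3.83 ± 0.0217 CPM in WT against its rise in Arg51Leu. The rise of row 14934 was larger in Arg51Gln than in WT by a log2 fold of 0.38 (SE 0.04, adjusted p = 0.000108), and in Arg51Leu it differed from Arg51Gln by -0.33 (SE 0.05, adjusted p = 0.00621). Row 31331 differed between Arg51Gln and WT by -0.25 (SE 0.04, adjusted p = 0.0449), with 1352 ± 22.9 to 1630 ± 51 CPM in WT and 1288 ± 51.5 to 1305 ± 20.8 CPM in Arg51Gln. The last call was lost with limma-voom (adjusted p = 0.235) and without any 1 of 8 libraries, those of WT OFF, Arg51Leu ON and Arg51Gln ON, WT ON replicate 2 and Arg51Gln OFF replicate 2 (adjusted p of 0.0504 to 0.273), and that of row 14934 between the mutants with limma-voom (0.21) and without Arg51Leu OFF replicate 2 (0.056) or Arg51Gln OFF replicate 1 (0.057).

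These were all the calls: 2 rows between Arg51Leu and WT, 3 between Arg51Gln and WT and 1 between Arg51Leu and Arg51Gln. At an unadjusted p below 0.05 there were 838, 1535 and 1408 rows where 1030 are due by chance, and DESeq2 called 7 (3 higher, 4 lower), 12 (4 higher, 8 lower) and 24 (21 higher, 3 lower). Of the rows named by the smallest p without passing, row 41839 did not pass in Arg51Leu against WT (log2 difference -2.74, SE 0.48, adjusted p = 0.0867), and neither did row 49011 (-0.37, SE 0.06, adjusted p = 0.112), row 17735 (0.21, SE 0.04, adjusted p = 0.187) or row 21655 (1.10, SE 0.21, adjusted p = 0.187) in Arg51Leu against Arg51Gln. Row 41839 passed without WT OFF replicate 2 (0.043) or Arg51Leu ON replicate 2 (0.0325) and with no filter on low counts (9.47e-06), and row 49011 passed without Arg51Leu ON replicate 2 (0.0313) and with no filter (0.000979). Row 21655 passed without Arg51Leu ON replicate 2 (0.0449) and with no filter (0.000206), and row 17735 with DESeq2 (5.45e-05) and with no filter (3e-04). For Arg51Leu against WT the count was 5 without WT OFF replicate 2, 6 and 4 without Arg51Leu OFF replicate 1 or 2, 5 and 6 without WT ON replicate 1 or 2, and 11 and 4 without Arg51Leu ON replicate 1 or 2. For Arg51Gln against WT it was 7 without either Arg51Leu OFF replicate, 19 without Arg51Gln OFF replicate 1, and 6 without WT ON replicate 1 or either Arg51Leu ON replicate. For Arg51Leu against Arg51Gln it was 6 and 4 without Arg51Leu OFF replicate 1 or 2, 0 and 2 without Arg51Gln OFF replicate 1 or 2, 7 and 23 without Arg51Leu ON replicate 1 or 2, and 4 and 3 without Arg51Gln ON replicate 1 or 2.

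With tetracycline, the rows named by the rule as highest in the Arg51Leu line over the WT line were row 41704, at 9.54 ± 0.186 against 0.348 ± 0.0577 CPM (log2 fold 4.76, SE 0.18, adjusted p = 2.8e-13), and row 4152, at 38.1 ± 0.635 against 1.66 ± 0.204 CPM (log2 fold 4.52, SE 0.10, adjusted p = 2.36e-17). Row 33217 was lower, at 1.92 ± 0.116 against 7.25 ± 1.17 CPM, and so was row 56024, at 3.1 ± 0.604 against 11.6 ± 0.365 CPM (adjusted p = 4.41e-05 and 0.00585). The rule took 2695 of the called rows into account, and rows outside it had larger folds, such as row41839 with a log2 fold of -3.14 (adjusted p = 5.28e-06). Of 2937 called rows, 1353 were higher and 1584 lower, and 452 differed at least 1.5-fold, 361 of them higher and 91 lower. The balance of all called rows turned to 1681 higher and 1484 lower with no filter, 1485 and 1413 with 1 row per near-identical set, and 1471 and 1402 without Arg51Leu OFF replicate 2. The count was 1561 and 1708 without WT ON replicate 1 or 2, 1594 without Arg51Leu ON replicate 1, and 1833 with DESeq2.

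The Arg51Gln line with tetracycline had higher levels than WT of rows 41704 (7.95 ± 0.188 CPM) and 9167 (10.9 ± 0.064 against 0.601 ± 0.306 CPM), with log2 folds of 4.5 (SE 0.18) and 4.17 (SE 0.24) and adjusted p of 6.51e-13 and 1.14e-09. Rows 6052 and 16049 were lower, at 0.549 ± 0.0783 against 5.46 ± 0.43 CPM and 0.513 ± 0.028 against 2.86 ± 0.0247 CPM, with adjusted p of 1.65e-10 and 1.22e-08. There were 3682 called rows, 1665 higher and 2017 lower; of the 603 that differed at least 1.5-fold, 386 were higher and 217 lower. The count was 2227 without WT ON replicate 2, 2351 without Arg51Gln ON replicate 2, and 2443 with DESeq2.

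Without tetracycline the lines already differed. In Arg51Leu against WT, rows 41704 (9.03 ± 0.14 against 0.346 ± 0.105 CPM) and 4152 (37.7 ± 1.32 against 1.63 ± 0.325 CPM) were again the highest by fold under the rule, and row 33217 (0.934 ± 0.409 against 7.87 ± 1.35 CPM) was the lowest, with adjusted p of 3.96e-13, 1.51e-17 and 1.92e-06. Row 26831 was lower as well (99.2 ± 6.6 against 341 ± 113 CPM, adjusted p = 0.0474), a call lost without any 1 of 10 libraries, all but the Arg51Gln OFF pair, with adjusted p of 0.0591 to 0.212, and also with no filter (0.0879), with only the libraries compared (0.147) and with thinning (0.0513). In Arg51Gln against WT, rows 41704 (7.62 ± 0.377 CPM) and 9167 (9.64 ± 0.231 against 0.946 ± 0.347 CPM) were higher, and rows 6052 (0.62 ± 0.139 against 6.2 ± 0.196 CPM) and 783 (1.11 ± 0.15 against 4.32 ± 0.012 CPM) were lower, with adjusted p of 6.81e-13, 5.61e-09, 7.37e-11 and 2.68e-08. The calls were 2962 for Arg51Leu (1457 higher, 1505 lower, 408 by at least 1.5-fold, 314 of them higher) and 3207 for Arg51Gln (1623 higher, 1584 lower, 560 by at least 1.5-fold, 341 of them higher). For Arg51Leu the balance turned to 1126 higher and 1022 lower without WT OFF replicate 1, 1102 and 964 without Arg51Leu OFF replicate 1, 773 and 765 without replicate 2, and 1531 and 1404 with 1 row per near-identical set. For Arg51Gln it turned to 1092 and 1163 without WT OFF replicate 2 and 1028 and 1085 without Arg51Gln OFF replicate 2. For Arg51Leu the count was 1658 without WT OFF replicate 2 and 1538 without Arg51Leu OFF replicate 2, and for Arg51Gln it was 2113 without Arg51Gln OFF replicate 2; DESeq2 called 1921 and 2124.

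**Figure D3:**
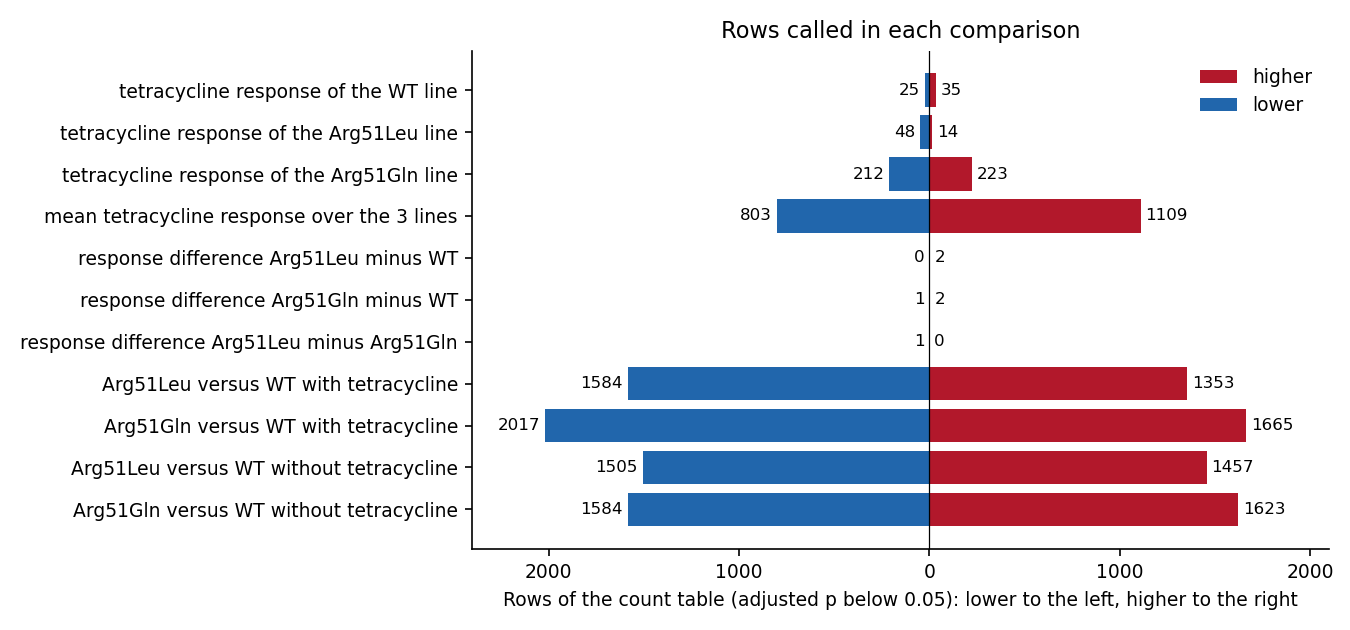
Number of rows with an adjusted p below 0.05 in each comparison (edgeR), with rows higher in the first-named condition to the right and lower rows to the left of 0 on a linear axis. The differences between lines hold 2937 to 3682 rows, the single responses 60 to 435 and the differences between responses 1 to 3.

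The line differences with and without tetracycline were largely shared, in libraries that do not overlap. Leaving out row 14934, 1910 rows were called in the same direction in both states for Arg51Leu against WT, where 211 are expected for independent lists, and 5 in opposite directions. For Arg51Gln it was 2102 rows where 286 are expected, and 2 in opposite directions. Of the rows called without tetracycline, 98% and 95.9% had the same direction with it. Across 14465 rows the 2 sets of log2 folds had Pearson correlations of 0.65 for Arg51Leu and 0.7 for Arg51Gln (Spearman 0.69 and 0.66).

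**Figure D4:**
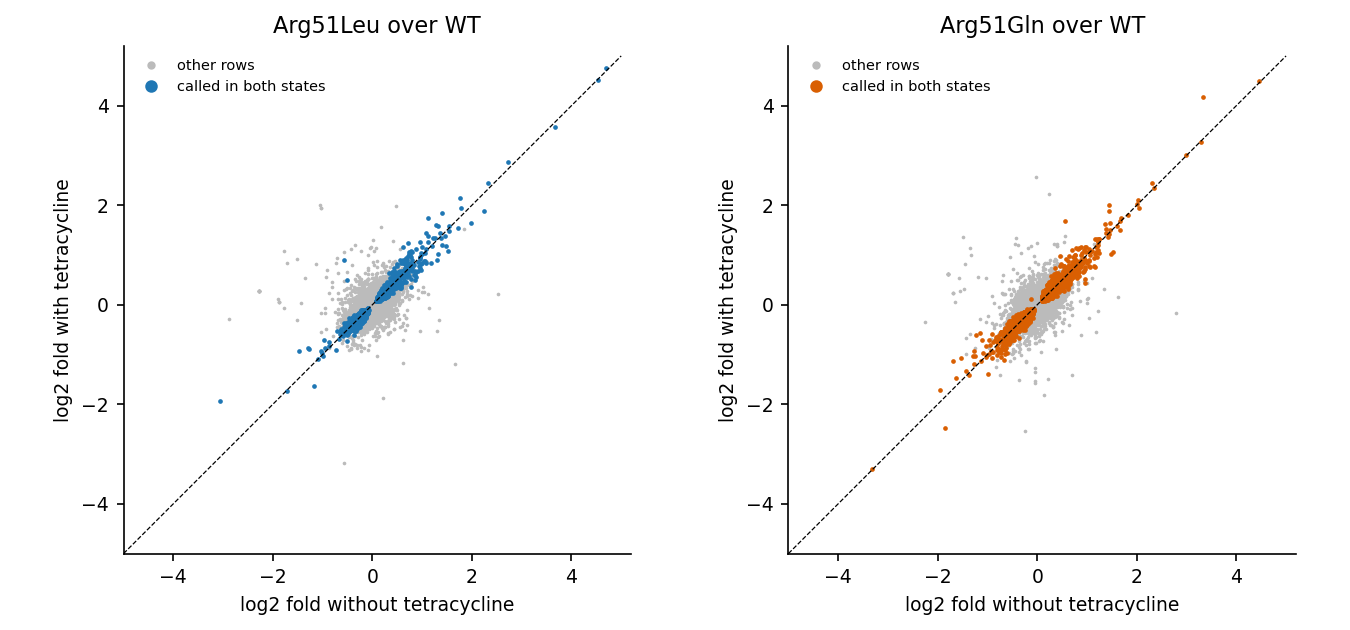
Log2 fold of each mutant line over WT with tetracycline (vertical) against that without it (horizontal), 1 point per row with a mean log2 CPM of at least 1; coloured points were called in both states and the dashed line marks equal folds. Most called rows lie near the dashed line, with Pearson correlations over all points but row 14934 of 0.65 for Arg51Leu and 0.7 for Arg51Gln.

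The 2 mutant lines also shared differences from WT. With tetracycline 409 rows were higher and 307 lower in both (109 and 155 expected for independent lists), and 287 went in opposite directions. Without it 454 were higher and 344 lower (115 and 116 expected), and 191 went in opposite directions. For opposite directions no expected number was computed in either state. Both comparisons use the same WT libraries: simulated mutant lines at the WT means shared 0.3 and 0.6 rows on average, and at most 3 and 2. Those lines held no differences and so had few calls to share, and the values do not measure how many real calls the common libraries bring together. The Pearson correlation was 0.36 with and 0.45 without tetracycline, below the simulated 0.51 and 0.49, and the Spearman correlation was 0.17 and 0.31. The covariance was 0.0196 with tetracycline against a simulated 0.00913, a difference of 0.0105, and 0.0248 without it against 0.00839, a difference of 0.0164. The 2 WT libraries of a state were not split between the comparisons, as this leaves 1 for each, so part of the excess may come from them. Between Arg51Leu with and Arg51Gln without tetracycline, which share no libraries, the Pearson correlation was 0.25, the Spearman correlation 0.17 and the covariance 0.0134. With the states exchanged they were 0.17, 0.06 and 0.0098. These comparisons still share the WT line, so a trait of that line alone enters both with the same sign. The overlaps and correlations therefore cannot tell an effect common to the 2 mutant forms from a trait of the WT line.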

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

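The search for an offsetting gain for row 17333 was chosen after its values had been seen; fits without each library were planned, but their use as a test of this row was set after their values had been seen. The 6 results below were listed because the test of the difference between the responses of 2 lines passed the threshold in edgeR. They involve 4 rows of the table. In the simulated difference of the Arg51Leu and WT responses 14 of 157 calls were unchanged rows, so false calls among the 6 are not excluded.

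Row 17333 responded to tetracycline 1.07 higher on the log2 scale in Arg51Leu than in WT and 1.13 higher in Arg51Gln, since it fell in the WT line and the levels of the mutant lines moved by -0.635 and -0.0657 CPM. A single odd library does not account for it: the highest adjusted p of either difference without any 1 library was 0.00868. Another possible explanation is that its reads were assigned to a different row. A search for rows that rose in the WT line, differed from both mutant responses at an unadjusted p below 0.01 and gained between 0.5 and 2 times the CPM lost found 5 rows, while the same search for gains in Arg51Leu found 2 and in Arg51Gln 14, so that the count decides nothing. In WT, 3 of the 5 rose past the threshold, row 55055 (adjusted p = 0.0199) and the near-identical rows 1581 and 61377 (0.000608 each). Rows 56024 (0.068) and 5473 (0.0736) did not. Rows 55055, 1581 and 61377 also rose in both mutant lines, and row 5473 moved by -3.32 and -6.48 CPM in Arg51Leu and Arg51Gln. Row 56024, named above, gained 8.3 CPM in WT and moved by -0.674 and -0.313 CPM in the mutant lines. Its sum with row 17333 was 21.41 CPM OFF and 19.85 CPM ON in WT. The replicates of rows 17333 and 56024 deviated from the group mean in opposite directions in 3 of 6 groups. In the rest, WT OFF and WT ON among them, they deviated alike. Over the 5 rows found, opposite deviations from row 17333 occurred in 2 to 4 groups. These values were looked up after the search, and the explanation of moved reads stays open. The substitution stays open as the biological explanation, and it cannot be told apart from the line, because the design has 1 line per genotype.

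Row 21664 had a response difference of 1.47 between Arg51Leu and WT. The rise of row 14934 was 0.38 larger in Arg51Gln than in WT, and its difference between Arg51Leu and Arg51Gln was -0.33. Row 31331 had a response difference of -0.25 between Arg51Gln and WT.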

How the results depend on the processing

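Thinning to equal totals and keeping 1 row per near-identical set were chosen after the data had been seen. The 42 results for single rows had 889 alternative values, none with the opposite sign; 80 values for 12 results lost the call, 10 values for 4 gained it, and DESeq2 gave no adjusted p in 14 cases, which were left out. RLE factors, the filter of 1 CPM in 4 libraries, thinning and the near-identical sets kept each of the 11 counts of calls within 1.5 times, but with thinning rows 53638 (adjusted p = 0.0689), 35713 (0.0508), 20577 (0.0607) and 26831 (0.0513) were not called. Counts below are in the order WT, Arg51Leu and Arg51Gln response, then the response differences Arg51Leu minus WT, Arg51Gln minus WT and Arg51Leu minus Arg51Gln, and a setting lists those that moved by more. With a fold of at least 1.5 the responses had 8, 9 and 9 calls, the mean response 25, the last 2 differences 1 and 0, and the mutant lines against WT 452 and 603 with tetracycline and 408 and 560 without it, for Arg51Leu and Arg51Gln; these falls follow from the added condition. With DESeq2 the first 2 responses had 150 and 97 calls, the differences 7, 12 and 24, and the lines 1833, 2443, 1921 and 2124. With limma-voom the responses had 9, 8 and 109 calls and the last difference 0, where edgeR called 1 and 1408 rows had an unadjusted p below 0.05. With no filter on low counts the responses had 299, 331 and 973 calls and the differences 77, 147 and 84. With only the libraries of the groups compared the WT response had 119 calls and the differences 4, 25 and 2. The cause of these changes was not tested.

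Replicate numbers were shared between groups. The 15 correlations between groups of the difference of replicate 1 and 2 ran from -0.0719 to 0.0651 (within a line -0.0615 to 0.0245), so the numbers were not taken to pair the libraries. With the replicate block the differences had 4, 5 and 2 calls and the other counts stayed within 1.5 times; rows 35713 (adjusted p = 0.0577), 20577 (0.0514) and 26831 (0.0687) were not called and row 41839 was (0.0455). With the number as a block within each line the responses had 22, 38 and 126 calls and the differences 11, 11 and 10, and rows 53638 (0.0921), 35713 (0.134), 19680 (0.071), 20577 (0.0517) and 58281 (0.0663) were not called.

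Leaving out 1 library at a time gave 9 to 93 calls in the WT response, 14 to 55 in Arg51Leu, 9 to 732 in Arg51Gln and 1260 to 2093 in the mean response. The differences had 2 to 11, 2 to 19 and 0 to 23 calls. Arg51Leu against WT had 1561 to 2953 with and 1538 to 3158 without tetracycline, and Arg51Gln 2227 to 3834 and 2113 to 3389. Lower counts are in part due to fewer samples, and small folds were recovered in part in simulated data with all libraries. The gene list tests and the MAB21L1 level, with their alternatives, were not run. Overlaps of responses at an adjusted p below 0.1 were 18 higher and 30 lower rows for WT and Arg51Leu, 47 and 21 for WT and Arg51Gln, and 24 and 41 for Arg51Leu and Arg51Gln.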

Other observations

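The tests of equal depth and of transgene leak in this part were chosen after the values they measure had been seen; those of other splits and of fold sizes were not. The mean tetracycline response had 1912 calls. Among 100 of the 462 splits of the 12 libraries into 6 and 6, only the real one (1 of 100) gave as many, and the highest of the others was 26. Many of those splits are unbalanced between lines, and lines hold most of the variance. Of 100 of the 108 splits with 2 and 2 libraries of each line, again only the real one (1 of 100) gave as many and the highest of the others was 7, so a random split is excluded as the source of that count. The test does not bear on whether tetracycline itself or the transgene is behind it.

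The Arg51Gln response had 435 calls against 60 and 62 in the other lines. Unequal depth is argued against by the totals: the Arg51Gln libraries held 26257719 to 28914844 counts, within the WT range of 25944002 to 29388508. At equal totals Arg51Gln had 6.65 times the calls of the next line, but thinning could change little between lines so alike in depth. Larger folds of the same rows are a candidate explanation that stays open. Over the 1911 rows of the mean response, the median log2 folds aligned to that response were 0.115 in Arg51Gln, 0.0997 in WT and 0.097 in Arg51Leu. To show the spread, the ON and OFF libraries of a line were set against each other by replicate number, which does not pair them. The medians were then 0.113 and 0.115 in Arg51Gln, 0.113 and 0.0861 in WT and 0.0807 and 0.117 in Arg51Leu. The criterion set beforehand, that both Arg51Gln values lie above all values of the other lines, was not met. The lower Arg51Gln value lay -0.004 from the highest of the others, which is within their spread. That allowance for spread was not part of the criterion, and the explanation is left open because of it. The count itself fell to 9 without Arg51Gln OFF replicate 2 and to 15 without Arg51Gln ON replicate 2, and the responses of Arg51Gln and WT differed in 3 rows by the direct test.

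Row 14934, the most induced row with a mean log2 CPM of at least 1, had 34.1 to 79.6 CPM without tetracycline, and if it reports the transgene, which was not established here, some of the line differences before induction could come from leak. A leak effect in proportion to that level, if complete within the 12 h of induction, needs differences that grow severalfold with induction. Among rows called with tetracycline, the median difference was 1.2 times that without it for Arg51Leu and 1.33 times for Arg51Gln, although this choice of rows favours the state with tetracycline; among rows called without it, the ratios were 0.837 and 0.858. A proportional leak effect that is complete within 12 h is therefore argued against for these medians. An effect that takes longer than 12 h to build up, or is already saturated at the OFF level, was not tested. The medians also do not exclude leak behind some of the rows. Differences between cell lines unrelated to the transgene remain a possible explanation, and cannot be told apart from effects of the substitutions with 1 line per genotype.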
